A study of Homo sapiens with 4 samples.

How the data were processed

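RNA sequencing of the human glioma cell line GBM8401 was analysed in 4 libraries, 2 from the parental line and 2 from a temozolomide-resistant line derived from it. Temozolomide (TMZ) is the alkylating drug used against glioblastoma. Per the labels' protocols, the resistant line was raised in medium with 200 µM TMZ over 140 days, total RNA was taken with Trizol, and libraries were made with a strand-specific kit from Agilent. Samples were grouped by the treatment named in their labels. The labels number the replicates 1 and 2 in each group and call them biological, but they tie no number to a shared day or culture, and both resistant libraries come from a single derived line. The p-values therefore measure the spread between these cultures, not between independently derived resistant lines.

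The authors deposited 1 table of gene-level values for 58219 Ensembl gene IDs, with 1 column per library. Per the submitters' processing notes, the tools were bcl2fastq, Trimmomatic 0.36, HISAT2 2.1.0, SAMtools 1.2 and Cufflinks 2.2.1 with Cuffdiff, on build GRCh38.p10. The settings, the annotation release, the scaling method and the strand setting of the counting are not given in the sources used here. The deposited values are a signal that is never negative: fragment numbers per gene multiplied by a factor for each library, not divided by gene length. Dividing each library's values by its step (0.814, 0.956, 0.753 and 0.849 per fragment) gave whole numbers within 0.05 for 91.2% to 94.1% of the values above 0, and for 95.8% to 96.1% of values of at most 20 fragments. The remainder holds fractions, as arises where fragments are divided among genes. The deposited totals were 23163310 to 25832511, which the steps translate to 27019114 to 30759700 fragments, so depth was similar in both groups. Because the deposited values were scaled and not whole, the count-based test planned before the data were examined was replaced by limma on log values. The plan had foreseen rounding values that are not whole, so the replacement was a choice. That choice and its settings were made after the unit of the values was known and before any test was run.

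Genes were kept where the deposited value was at least 10 in at least 2 libraries and summed to at least 15. The authors' scaling was left as deposited. Values were analysed as log2(value + 1) in limma 3.58.1 (R 4.3.3), with a mean-variance trend and robust empirical Bayes moderation. The model held the group alone, the tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method, with an adjusted p under 0.05 counted as a change. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Means are given with the SD of the 2 libraries of a group, and log2 fold changes with their standard error (SE).

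Gene classes, coordinates (GRCh38, counted from 1) and the long noncoding RNA (lncRNA) set come from GENCODE 29, which held 57881 of the IDs. Symbols come from a gene name table that held 57378 of them. The 338 IDs left without a symbol carried at most 0.017% of the signal of a library. GENCODE 29 and the processing notes both use GRCh38, but the authors' annotation release may differ. Because the strand setting is not given, fragments of a gene and of an antisense partner cannot be told apart, and overlapping genes are named beside some of the genes concerned.

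Before the data were examined, 41 gene lists were fixed: DNA repair pathways, isocitrate dehydrogenases and the tricarboxylic acid cycle, stress and growth pathways, glioma cell states, lncRNAs discussed in glioma, markers of other cell types, and genes that report on RNA quality. Lists with 5 or more tested members were compared with all other genes by limma's camera test with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the residuals. The fry test, which asks whether the genes of a list move one way on balance, was run beside it. Melanocyte markers had too few tested members. Another 7 lists were composed after the data were seen and appear only among the additional observations.

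Named genes followed a rule also fixed before the data were examined. It takes a set of genes of alkylation repair, mismatch repair and isocitrate dehydrogenase. It adds the 7 protein-coding genes with the largest called rise and the 7 with the largest called fall at a mean log2 CPM of at least 3 (the value relative to the library's total), without overlap between the groups. It does the same with 3 and 3 lncRNA genes at a mean log2 CPM of at least 0, and it takes up to 4 members with the smallest adjusted p from each list past the camera test and from each list on alkylation repair or isocitrate dehydrogenase. Genes of the Y chromosome, XIST and TSIX were never eligible. The plan skipped IDs without a symbol, and genes with a clone-based name were skipped with them, so larger changes among those are not named. Members named because they ran against the direction of their list, or because few members changed, were picked after their values were seen. Not every gene that the rule picks is described here.

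The procedure was tested on simulated data with the levels of the real libraries, a spread smoothed over genes of like level and 200 changed genes. Of the simulated genes 15846 passed the filter. For the comparison of resistant with parental cells the procedure recovered 61.2% of 1.5-fold, 73.1% of 2-fold and 98.5% of 4-fold changes. It called 8 of 15932 unchanged genes, some of which had not passed the filter and could not be called. The p-value adjustment is stricter where few genes change, so these shares do not carry over to the real data, where 5991 genes were called. The smoothed spread leaves out differences between genes, so false calls may be undercounted. Of 200 simulated lists of 30 unchanged genes, 0% reached an unadjusted camera p under 0.05. The simulated genes were drawn independently of one another. That share therefore does not show how often lists of correlated genes pass falsely, and the real replication list had an estimated correlation of 0.269.

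Alternatives planned before the data were examined were median-of-ratios size factors, scaling to library size alone, limma-voom on the step-divided values, no filter, a filter of 1 CPM in 2 libraries, a test against a fold change of 1.5, each library left out in turn and the replicate number as a block. After the data were seen, pseudocounts of 0.5 and 5 and a correction for transcript GC content and length were added. Trimmed-mean (TMM) factors in the limma fit on log values were also added then. The planned count-based test had TMM factors as its scaling, and the deposited scaling took their place. No variants were called, since a table of gene values holds none, and IDH mutations were not analysed here.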

Results

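Gene expression was compared between parental GBM8401 cells, a human malignant glioma line, and a GBM8401 line made resistant to temozolomide (TMZ) in 200 µM of the drug over 140 days. TMZ methylates DNA, and its most toxic product, O6-methylguanine, is removed by the protein MGMT or else engages mismatch repair. The study set out to profile mRNAs and long intergenic noncoding RNAs linked to drug resistance. Each group held 2 libraries. Deposited totals were 24791254 and 25832511 scaled fragments for the parental libraries and 23163310 and 24225039 for the resistant ones. Replicates correlated at a Pearson r of 0.989 (parental) and 0.991 (resistant) over log2 values of the genes tested, against 0.965 to 0.971 between groups. The labels call the replicates biological, and each library was counted as a sample. Genes are not independent replicates, and these correlations describe the libraries only.

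Resistant cells differed from parental cells across a large part of the transcriptome. As lists tested with a preset inter-gene correlation, DNA replication, mitosis, mismatch repair and homologous recombination genes were lower in resistant cells, while p53 targets, amino acid stress genes, inflammatory genes and ribosomal protein genes were higher. None of these lists passed with an estimated correlation. MGMT and most changed lncRNAs were higher as well. Of 16132 genes tested, 5991 changed (limma, adjusted p under 0.05), 2621 higher and 3370 lower in resistant cells. Changes of at least 2-fold were more often upward, with 870 genes higher and 486 lower, and 146 rose and 83 fell by at least 4-fold. In 11066 genes the libraries of one group lay entirely above those of the other, where chance gives 33.3% of genes. The split between higher and lower genes depended on scaling: 43.8% of the changed genes were higher with the deposited scaling and 56.9% with scaling to library size alone. With TMM factors, the scaling of the planned count-based test, 6348 genes changed and 49.8% of them were higher. Without resistant replicate 1 the count of changed genes was 3593, and without resistant replicate 2 it was 3842. Tested against a fold change of 1.5 in place of any change, 601 genes passed, 325 higher and 276 lower.

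MGMT, which removes methyl groups from O6-methylguanine and is the main enzyme of TMZ resistance, was nearly silent in parental cells and expressed in resistant cells. Its deposited value (gene ENSG00000170430, chromosome 10, 129467184 to 129768007, plus strand, overlapping AL157832.2 on the other strand) was 17.1 and 3.82 in the parental libraries and 515 and 586 in the resistant ones. The means were 10.4 ± 9.38 (SD, n = 2) and 550.5 ± 50.2 (SD, n = 2), a log2 fold change of 5.88 ± 0.59 (SE) or 58.9-fold (limma, adjusted p = 9.08e-04). The size of the fold rests on the low parental values. It was 6.83 on the log2 scale without parental replicate 1 and 4.93 without parental replicate 2, and the call held in both. MGMT was the 1 called gene among the 7 of the O6-methylguanine and alkyl repair list. The other members with the smallest adjusted p, ASCC1, MPG and ASCC2, had log2 fold changes of 0.20, 0.19 and −0.15 that did not pass the test. The list as a whole did not pass (adjusted p = 0.27, and 0.766 with an estimated correlation), and 1 member was called when adjusted over the list alone.

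Mismatch repair genes were lower in resistant cells. MSH6 (chromosome 2, 47695530 to 47810101) fell 1.90-fold, from 7903 ± 29.9 to 4157 ± 183 (SD, n = 2). It encodes a subunit of a mismatch sensor. Its log2 fold change was −0.93 ± 0.07 (SE), with an adjusted p of 1.01e-04. PMS2 had a log2 fold change of 0.03 ± 0.11 (adjusted p = 0.876). Of the 19 mismatch repair genes, 14 fell and 0 rose, 15 when adjusted over the list alone, with a median log2 fold change of −0.44. Among them were EXO1, the exonuclease of the pathway, 1.94-fold lower, and PCNA, the sliding clamp, 1.82-fold lower. The list passed camera (adjusted p = 1.85e-05) but not with an estimated correlation (adjusted p = 0.508). PCNA, the replication factor C and the replication protein A genes of this list also serve DNA replication. The fall of the list was not separated from that of the replication genes. MSH6 overlaps FBXO11 on the other strand.

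Homologous recombination and Fanconi genes moved in the same direction. Of 29 members 19 fell and 0 rose, 20 when adjusted over the list alone, with a median of −0.44 (camera adjusted p = 6.86e-06, and adjusted p = 0.508 with an estimated correlation). BRIP1 was 1.84-fold lower, the BLM helicase 1.74-fold and BRCA1 1.64-fold. The fall of this list, too, was not separated from that of the replication genes. In base excision repair, which removes the N-methylated bases that TMZ also makes, 6 of 20 genes fell and 0 rose, 4 when adjusted over the list alone. The list did not pass (adjusted p = 0.331, and 0.886 with an estimated correlation). FEN1, which overlaps FADS2 on the same strand and TMEM258 on the other, was 2.27-fold lower, the uracil glycosylase UNG and the thymine glycosylase TDG were each 1.65-fold lower, and PARP1 was 1.38-fold lower. MPG, the glycosylase for methylated purines, and APEX1, the abasic site endonuclease, had log2 fold changes of 0.19 ± 0.10 and −0.14 ± 0.07 (adjusted p = 0.163 and 0.158).

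The isocitrate dehydrogenase genes named in the title of the study differed little. IDH1 (chromosome 2, 208236227 to 208266074) had a mean of 2299 ± 65.6 in parental and 2675 ± 45.5 in resistant cells, and IDH2 (chromosome 15, 90083045 to 90102504) of 2147 ± 171 and 2495 ± 54.5 (SD, n = 2). Both gave a 1.16-fold difference that did not pass the test (adjusted p = 0.0525 and 0.0772). IDH1 passed in 7 and IDH2 in 6 of 15 alternative settings, always as higher. Both passed with TMM factors, the scaling of the planned count-based test. Of the 24 genes of the list with the tricarboxylic acid cycle, 3 rose and 3 fell, 6 when adjusted over the list alone, and the list did not pass (adjusted p = 0.477, and 0.766 with an estimated correlation). MDH1 rose 1.46-fold, while IDH3A, a subunit of the NAD-dependent enzyme, fell 1.30-fold and fumarase (FH) 1.30-fold. The malic enzyme ME2 was 1.35-fold lower.

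**Figure D1:**
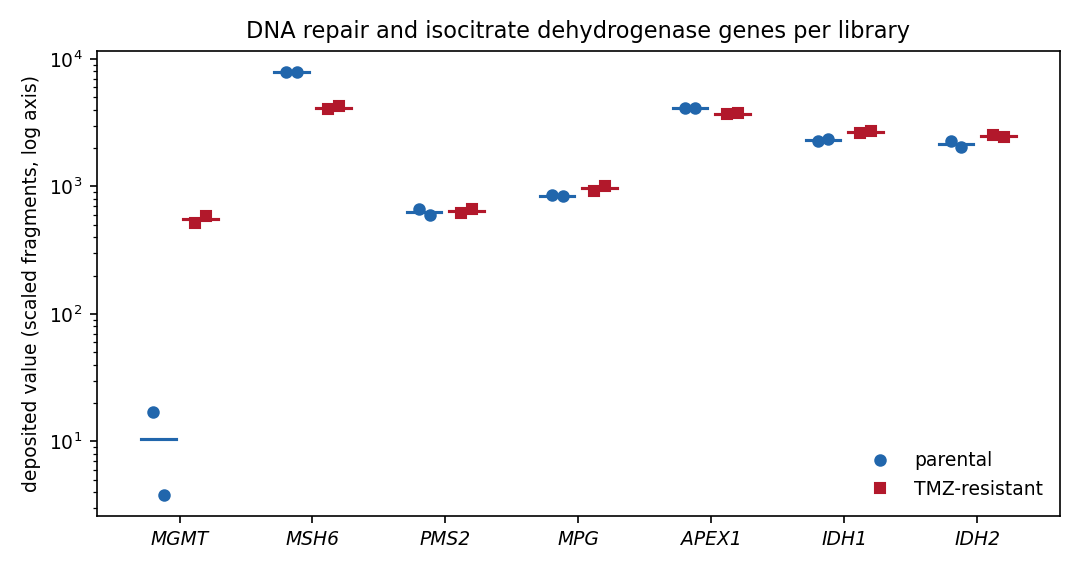
Deposited values (scaled fragments, log axis) of 7 repair and isocitrate dehydrogenase genes in the 2 parental (circles) and 2 TMZ-resistant (squares) libraries, with bars at the group means. MGMT lies at 3.82 and 17.1 in parental and at 515 and 586 in resistant libraries, and MSH6 is lower in resistant cells without overlap.

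Among protein-coding genes at a moderate or high level, without overlap between groups and without clone-based names, the largest called rises were in 7 genes. SAA2 rose 19.7-fold and SAA1 10.4-fold (log2 fold changes 4.30 ± 0.15 and 3.38 ± 0.14, SE). These serum amyloid A genes on chromosome 11 are near-identical copies, so fragments may be divided between them with error. TNFRSF6B, a decoy receptor for Fas ligand, rose 15.6-fold from 375 ± 84.9 to 5786 ± 407 (SD, n = 2), and it lies within the read-through gene RTEL1-TNFRSF6B on the same strand of chromosome 20. GDF15, a stress-induced cytokine, rose 14.6-fold from 422 ± 26.9 to 6190 ± 538. The immediate early transcription factor EGR1 rose 8.82-fold, SCART1 7.72-fold and DEPP1 7.37-fold. SCART1 lies on distal chromosome 10 (133453928 to 133523558) and overlaps CYP2E1 on the same strand. The adjusted p of these 7 genes ran from 1.24e-06 to 1.51e-04.

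The largest called falls under the same conditions were in 7 genes. CAPN6, a calpain without protease activity, fell 8.64-fold from 812 ± 8.76 to 93.4 ± 10.8 (SD, n = 2; log2 fold change −3.11 ± 0.14, SE). The mitochondrial co-chaperone gene DNAJC15 fell 6.37-fold, TMEM71 6.04-fold, the keratin gene KRT81, which overlaps KRT86 on the other strand, 5.49-fold and SPOCD1 5.34-fold. TNC, which encodes the matrix glycoprotein tenascin C, fell 5.12-fold from 2896 ± 244 to 565 ± 48.6. EDN1, the precursor of the vasoconstrictor endothelin 1, fell 4.60-fold. Their adjusted p ran from 1.36e-05 to 4.86e-05, and all 14 of these genes passed in each of the 15 alternative settings.

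**Figure D2:**
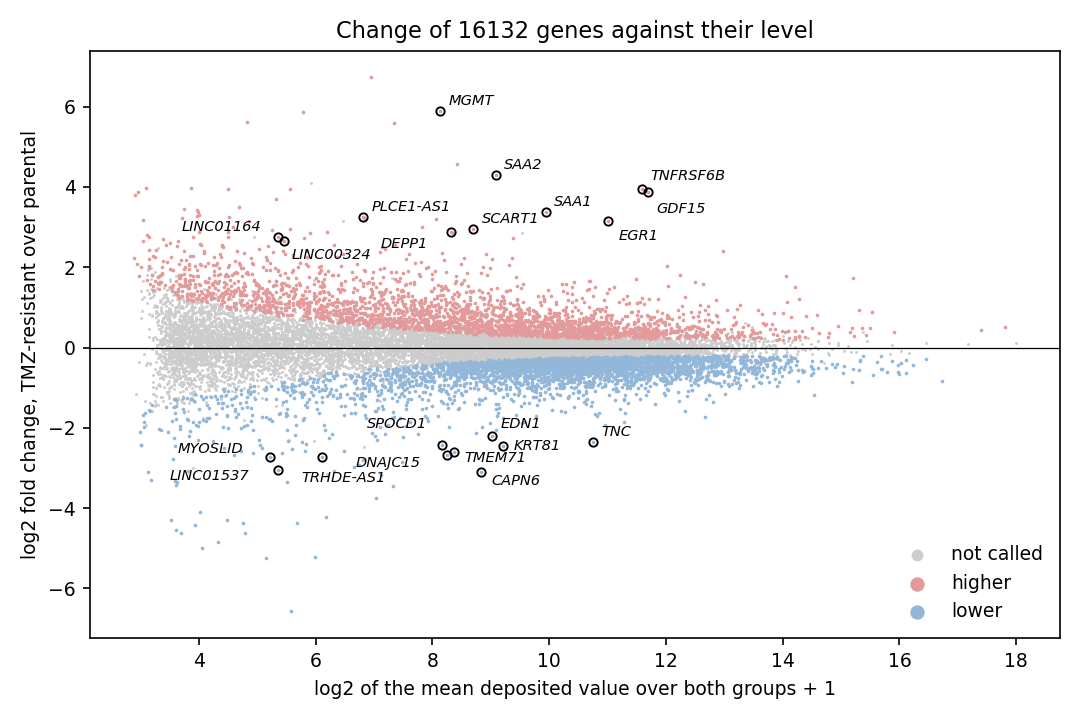
Log2 fold change of each tested gene (TMZ-resistant over parental) against the log2 of its mean deposited value plus 1, with genes called higher in red, called lower in blue and not called in grey. Circles mark MGMT at 5.88 and the 14 coding and 6 lncRNA genes picked by the naming rule. These have the largest called changes above their minimum levels among genes without overlap between groups, clone-based names left out.

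Of the 40 gene lists that could be tested, 14 passed camera, 8 as higher and 6 as lower in resistant cells. Lists were not matched for level, although genes at low levels tended to be higher in resistant cells, so small list medians may partly follow level. With an estimated correlation, a test that rests on few residual degrees of freedom here, 0 of the 40 lists passed camera and 2 of the 14 had an unadjusted p under 0.05 (interferon response and G2/M genes). The adjusted p of the 14 lists was then 0.508 except where given. By fry 9 lists passed, 8 of them among the 14, and the remaining list was that of oligodendrocyte markers. The 6 of the 14 that did not pass fry were ribosomal proteins (adjusted p = 0.0534), ATF4 and amino acid stress targets (0.0589), aldehyde dehydrogenases and glutathione transferases (0.0951), autophagy and lysosome genes (0.101), YAP and TEAD targets (0.139) and mitochondrially encoded genes (0.375).

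Genes of the cell cycle were lower. Of 31 G1/S and replication genes 28 fell and 0 rose (30 adjusted over the list alone), with a median log2 fold change of −0.78 (camera adjusted p = 8.85e-14). GINS2, of the replicative helicase, was 2.43-fold lower, SLBP, which binds the stem loop of histone mRNAs, 2.37-fold, the ribonucleotide reductase gene RRM2 1.94-fold and the helicase gene MCM4 1.94-fold. Among 32 G2/M and mitosis genes 25 fell and 1 rose (28 adjusted over the list alone), with a smaller median of −0.40 (camera adjusted p = 1.85e-08). The fall was 1.86-fold for CDC20, 1.71-fold for CCNA2, 1.68-fold for ANLN and 1.62-fold for PLK1, and the member that rose was the phosphatase gene CDC25C, at 0.31.

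Targets of p53 were higher, with 18 of 26 rising and 0 falling (18 higher and 1 lower adjusted over the list alone), and a median of 0.71 (camera adjusted p = 2.04e-09). Beside GDF15 these included CDKN1A, the cell cycle inhibitor p21, 2.98-fold higher at 9590 ± 108 against 3213 ± 27.4 (SD, n = 2), TP53INP1 at 3.01-fold and FDXR at 2.72-fold. Of 26 ATF4 and amino acid stress targets 22 rose (23 called adjusted over the list alone), with a median of 0.83 (camera adjusted p = 5.34e-11), and STC2 fell by 0.28. DDIT3 was 3.66-fold, ATF3 3.40-fold, the cystine transporter gene SLC7A11 3.17-fold and the serine synthesis gene PHGDH 1.79-fold higher.

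Inflammatory and interferon genes were also higher. In the NF-kB list 12 of 21 members rose (15 called adjusted over the list alone), with a median of 0.93 (camera adjusted p = 1.52e-05). SAA1 and SAA2 led it, ICAM1 was 2.73-fold and the cytokine gene LIF 2.42-fold higher, and IL11 fell by 2.93 on the log2 scale. In the interferon list 21 of 39 rose and 2, IFI44 and CMPK2, fell (23 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 9.72e-07). TRIM22 was 2.99-fold, IFIT2 2.55-fold, IFI35 1.96-fold and STAT2 1.95-fold higher. IFIT2 lies on distal chromosome 10, where genes were higher as a block, and its rise was not separated from that of the block. The antigen presentation list, with 2 of 13 tested members higher, did not pass (adjusted p = 0.296). Its values are incomplete, since 64.4% of the 180 coding genes between 29 and 34 Mb of chromosome 6 were listed at 0 in every library, against 13.2% of other coding genes. RPS18 and CLIC1, which most cells express, were among them, so a 0 there is not read as absence of expression.

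Genes of the epithelial-mesenchymal transition list were lower. Of these 13 of 23 fell (15 called adjusted over the list alone), with a median of −0.40 (camera adjusted p = 1.67e-03), and TGFB2 and ACTA2 rose. TAGLN was 3.17-fold, the repressor gene ZEB2 2.64-fold, TGFBI 2.26-fold and N-cadherin (CDH2) 2.11-fold lower. Aldehyde dehydrogenase and glutathione transferase genes passed as higher (11 of 29 higher, 3 lower, 14 adjusted over the list alone, median 0.28, adjusted p = 0.0267). GSTM1, which overlaps GSTM2 on the same strand, was 2.51-fold, ALDH6A1 1.90-fold and GSTO2 1.89-fold higher, and ALDH1B1 was 1.68-fold lower. Of 23 YAP and TEAD targets 11 rose and 6 fell (18 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.0267, and adjusted p = 0.766 with an estimated correlation). ANKRD1 was 3.47-fold, CCN2 1.83-fold and MYOF 1.75-fold higher, and the tissue factor gene F3 was 2.44-fold lower. ANKRD1 and MYOF, like GSTO2 above, lie on distal chromosome 10, where genes were higher as a block. Their rise was not separated from that of the block. Of 34 autophagy and lysosome genes 11 rose and 3 fell (14 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.0379). GABARAPL1 was 2.70-fold, NBR1 1.83-fold, WIPI1 1.56-fold and LAMP1 1.49-fold higher. Without parental replicate 1 neither of these last lists passed (adjusted p = 0.0997 and 0.104).

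Lists fixed as reports on RNA quality moved in part with the groups, and RNA quality itself was not measured. Ribosomal protein genes rose in 33 of 49 cases and fell in 0 (40 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 2.66e-10). RPL12 was 1.68-fold, RPL3 1.40-fold, RPL21 1.36-fold and RPS4X 1.32-fold higher. Of the 13 mitochondrially encoded genes 7 fell and 0 rose (7 adjusted over the list alone), with a median of −0.31 (camera adjusted p = 0.0379, and adjusted p = 0.766 with an estimated correlation). MT-ATP6 was 1.47-fold, MT-CO3 1.45-fold, MT-ND1 1.37-fold and MT-ND4L 1.24-fold lower. This call was lost without parental replicate 2 or resistant replicate 1, with a filter of 1 CPM and after correction for GC content and length, where the adjusted p reached at most 0.245. The share of signal from the whole mitochondrial chromosome was 3.62% and 3.77% in parental and 3.51% and 3.72% in resistant libraries. Dissociation and heat-shock genes went both ways (7 higher, 10 lower of 22, adjusted p = 0.521).

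Markers of other cell types did not pass camera as lists, and the oligodendrocyte markers, lower, passed fry (adjusted p = 0.0243). Among 12 epithelial markers KRT8 and KRT18 rose, and among 9 endothelial markers TIE1, CDH5 and TEK fell. CD68 was the 1 hematopoietic marker of 9 to rise, 1 of 10 fibroblast markers and 2 of 5 oligodendrocyte markers fell, and 1 of 6 neuron markers rose and 1 fell. Their camera adjusted p ran from 0.27 to 0.977.

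The remaining lists did not pass camera. Of 18 glioma stem cell genes 3 rose and 10 fell (adjusted p = 0.186), and of 46 matrix and adhesion genes 5 rose and 14 fell (0.262). Of 29 HOX gene IDs, with HOXC5 under 2 of them, 2 rose and 10 fell (0.27), of 24 hypoxia genes 3 and 9 (0.346), and of 29 neural progenitor-like glioma genes 2 and 7 (0.427). Glycolysis genes rose in 3 and fell in 5 of 20 cases (0.458), cholesterol synthesis genes in 6 and 5 of 23 (0.521), ABC transporters in 5 and 4 of 20 (0.528) and NRF2 targets in 6 and 4 of 22 (0.528). Astrocyte-like glioma genes rose in 6 and fell in 6 of 23 cases (0.591), receptor tyrosine kinases and ligands in 7 and 9 of 41 (0.738), mesenchymal-like glioma genes in 12 and 15 of 47 (0.78), apoptosis regulators in 6 and 9 of 33 (0.78) and unfolded protein response genes in 3 and 7 of 20 (0.783).

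**Figure D3:**
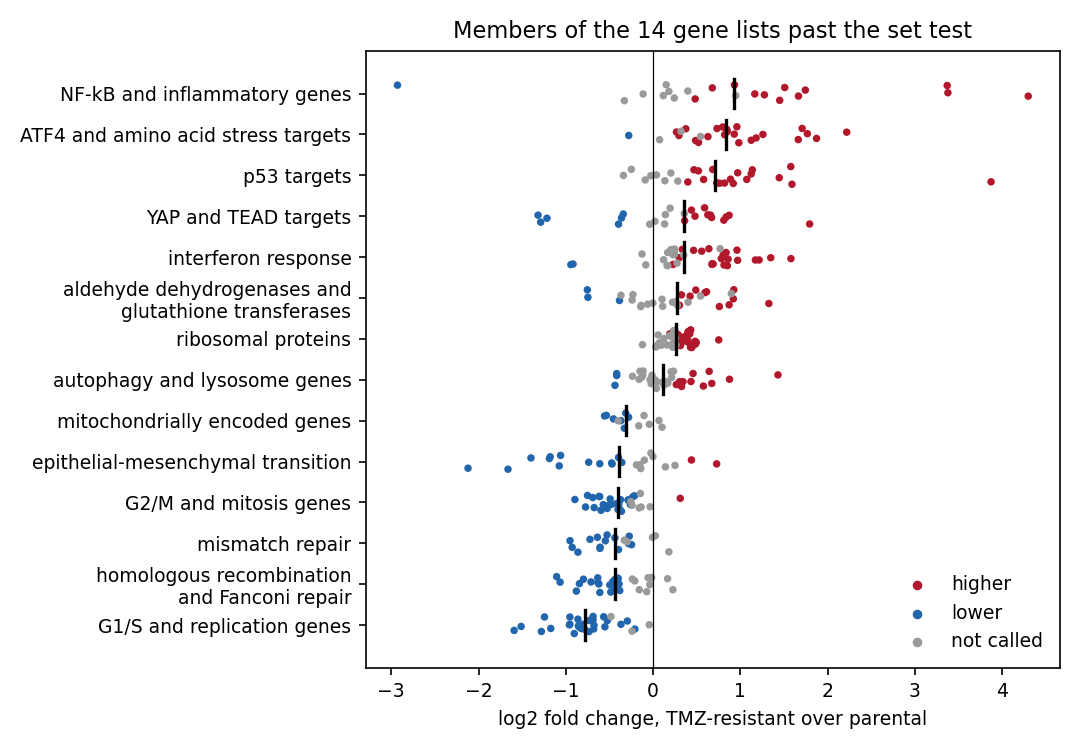
Log2 fold change (TMZ-resistant over parental) of each tested member of the 14 gene lists past the camera test, with members called higher in red, called lower in blue and not called in grey, and a black bar at each list's median. Replication genes have the lowest median (−0.78) and NF-kB and inflammatory genes the highest (0.93).

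Most lncRNAs that changed were higher in resistant cells. Of 1608 lncRNA genes tested 521 changed, 425 higher and 96 lower, and adjusted over the class alone 468 changed, 383 higher and 85 lower. For comparison, 2114 of the 5280 changed protein-coding genes were higher. The median log2 fold change was 0.34 over all lncRNA genes tested and −0.04 over protein-coding genes. The lincRNA class, on which the study focused, had 198 of 542 genes changed, 160 higher and 38 lower. PLCE1-AS1 (chromosome 10, 94279277 to 94287478) rose 9.52-fold from 20.5 ± 2.01 to 204 ± 1.49 (SD, n = 2), LINC01164 on distal chromosome 10 rose 6.73-fold, and LINC00324 on chromosome 17 rose 6.33-fold. LINC01537 on chromosome 11 fell 8.25-fold from 72.4 ± 10.4 to 7.92 ± 1.59, the smooth muscle lncRNA MYOSLID 6.68-fold and TRHDE-AS1 6.64-fold. The adjusted p of these 6 genes ran from 6.42e-05 to 5.86e-04. They were picked with clone-based names left out, so other lncRNA genes may have changed more. PLCE1-AS1 and TRHDE-AS1 overlap PLCE1 and TRHDE on the other strand, and fragments of the partners cannot be told apart. The list of lncRNAs discussed in glioma did not pass, with 12 higher and 7 lower of 44 IDs, LINC-PINT under 2 of them (19 adjusted over the list alone, adjusted p = 0.376).

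Precision was lower for lncRNAs, whose median level was 34.6 scaled fragments against 669 for protein-coding genes. Without resistant replicate 1 the count of changed lncRNA genes was 236 (183 higher, 53 lower), and without resistant replicate 2 it was 225 (170 higher, 55 lower). Without parental replicate 2, 57 were lower. Against a fold change of 1.5, 65 were higher and 14 lower.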

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

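The pseudocounts of 0.5 and 5 and the correction for GC content and length were chosen after the data were seen. So was the use of TMM factors in the limma fit, although TMM was the scaling of the planned count-based test. The other settings were planned. Among 15 alternative settings, 0 genes called in both a setting and the original fit changed direction. The count of 5991 changed genes stayed between 5842 and 6782 under other scalings, filters, pseudocounts, limma-voom and the GC and length correction, and at least 90.0% of the 5991 were shared. Of 90 genes picked by the naming rule, 85 to 90 kept their call in each of these settings. Scaling to library size moved the median log2 fold change of all genes from −0.02 to 0.08.

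Tested against a fold change of 1.5, 601 genes passed (325 higher, 276 lower, 560 at least 2-fold), 79 of them lncRNA genes (65 higher, 14 lower), and 37 of the 90 picked genes no longer passed, because the test asks for a larger change. Leaving out 1 library at a time, with the lone library taken to vary like the other group, gave 3593 to 5476 changed genes, 1348 to 2783 higher, 2079 to 3147 lower and 1000 to 1414 at least 2-fold. The lncRNA counts were then 225 to 494, with 170 to 437 higher and 53 to 70 lower, and 13 to 15 lists passed. The smallest counts, 3593 and 3842, came without a resistant library, against 5336 and 5476 without a parental one, and the cause was not tested. With the correlation estimated from the residuals, 0 lists passed camera and 9 passed fry.

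With the replicate number as a block, 8624 genes and 153 lower lncRNA genes passed, and 16 lists passed camera against 14 without the block. Deviations from the group means correlated at 0.27 across genes between same-numbered libraries, but with 2 pairs this does not establish a pairing, and the cause of the larger count was not tested. The planned count-model test and its second count-model alternative were not run, by choice, since the deposited values are scaled and not whole. The plan would have rounded such values. Simulated 1.5-fold changes were recovered in 61.2% of cases, so depth and 2 libraries per group limit what is said of small changes.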

Other observations

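The 7 gene lists of the next paragraphs were composed after the data were seen. The tests of level and of an extra copy on chromosome 10, of MGMT against its surroundings, of cycling cells and of the lncRNA genes were also chosen after the result was seen, and the correction for GC content and length was added after the data were seen.

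Values of histone genes rose while other replication genes fell, and how far the libraries capture histone mRNAs was not tested. Of 27 replication-dependent histone genes tested 13 were higher and 0 lower in resistant cells, with a median log2 fold change of 1.004 (limma's camera, adjusted p = 1.29e-06, and adjusted p = 0.196 with an estimated correlation). H3C6 rose 7.18-fold, H2BC4 4.33-fold and H2BC21 3.23-fold, from low levels of 13.7 to 176 scaled fragments, while SLBP, whose protein binds the 3' end of these mRNAs, fell 2.37-fold. Cytoskeletal genes went down. Of 27 actin cytoskeleton genes 18 fell and 1 rose (median −0.32, adjusted p = 3.6e-06, and 0.271 with an estimated correlation), among them ACTB from 139200 ± 13880 to 78640 ± 9995 (SD, n = 2). Of 10 tubulin genes 6 fell and 0 rose (median −0.54, adjusted p = 1.35e-03, and 0.342 with an estimated correlation), including TUBA1C, TUBB6 and TUBB4B. Among translation genes, 9 of 22 translation factors and related mRNAs rose and 1, NPM1, fell (median 0.19, adjusted p = 5.34e-04, and 0.269 with an estimated correlation), and 11 of 19 cytosolic tRNA synthetases rose and 4 fell (median 0.29, adjusted p = 9.43e-03, and 0.269 with an estimated correlation). Of these 11, 5 belong to the ATF4 list, and among the 14 synthetases outside it 6 rose and 4 fell (median 0.048). ZNF-named zinc finger genes rose in 113 and fell in 39 of 390 cases (median 0.19, adjusted p = 2.84e-04, and 0.269 with an estimated correlation). The median of each of these lists kept its sign under all 4 scalings compared. The lists were not compared with genes of like level. Outside the block on chromosome 10 described below, the median log2 fold change was 0.137 at the lowest and −0.136 at the highest levels, so small list medians may partly follow level.

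Cancer-testis genes moved far in both directions. USP26 rose 23.8-fold, from 26.7 ± 2.56 to 657 ± 39.03 (SD, n = 2), and CT55 rose 5.06-fold. MAGEC1 and MAGEA6 fell from 37.7 ± 8.75 and 52.4 ± 6.46 to 0.377 ± 0.53 and 1.18 ± 0.46, and MAGEA1 fell from 51.0 ± 7.67 to 8.20 ± 5.21. MAGEA genes have near-identical copies, so their fragments cannot be assigned with certainty. PAGE1, at 2861 ± 102 and 3050 ± 23.2, and SSX1, at 981 ± 39.1 and 902 ± 209, did not pass. As a list these 8 genes did not pass camera (adjusted p = 0.801, and 0.819 with an estimated correlation), and the sign of their median differed between scalings.

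Genes on distal 10q, MGMT among them, were higher as a block: from 86.75 Mb to the end of chromosome 10, limits placed by a change point on these fold changes, 154 of 295 genes rose and 13 fell (median 0.47, quartiles 0.15 and 0.83), against a median of −0.09 over the 383 other genes of the chromosome. Of 261 windows of 10 Mb in the genome, 2 had a median beyond the largest in 1000 shuffles (0.52), both within this block. In 1000 shuffles among genes of like level the largest was 0.588. Only 1 window, at 0.993 within the block, was beyond it, and the window from 100 to 110 Mb, at 0.569, was not. The tables argue against GC content and length as the cause, since 102.2% of the median was left after correction. They also argue against expression level. The change point took 47.46 off the sum of squares of the log2 fold changes, against at most 10.43 on any chromosome in 1000 shuffles among genes of like level, with the limits placed anew each time (chromosome 19, at 21.42, was also beyond). The windows of 10 Mb within the block had medians of 0.376 to 0.993. The block's median fell with level, from 0.656 to 0.503 and 0.371 in 3 groups of genes from lowest to highest, as did that of other genes of the same levels (0.137, −0.051 and −0.136). The excess over them was 0.519, 0.555 and 0.507 (95% bootstrap intervals over genes 0.248 to 0.700, 0.425 to 0.603 and 0.417 to 0.571). These intervals take neighbouring genes as independent and leave out the spread between cultures. An extra copy of the region may give such an excess, but the block's limits were chosen on these fold changes. RNA does not measure copy number, and no DNA was analysed here. MGMT lay 5.41 log2 units above the block's median (SE 0.59) and had the largest rise of its 295 genes, so a shift of the size of the median does not give its rise. Single genes of the block spread widely, with 13 others above 4-fold (4.42%, against 0.869% of genes outside the block). What raised MGMT beyond the block stays open.

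Replication genes were lower while p53 targets, ATF4 targets and ribosomal protein genes were higher. Transcript GC content and length do not account for it, since at least 89.7% of each of the 4 list medians was left after correction. Fewer cycling cells in the resistant cultures stay open as a cause of the lower replication genes. The same holds for the lower mismatch repair, recombination and base excision repair genes, which were not separated from them. The G2/M and mitosis list was lower in each of the 4 pairings of a resistant with a parental library (the highest median was −0.374), which restates the call of that list. MKI67 and TOP2A fell by only 0.214 and 0.26 on the log2 scale. From low levels, 13 of the 27 replication-dependent histone genes rose, a list that did not pass with an estimated correlation. How far the libraries capture histone mRNAs was not tested, so their rise is not counted for or against fewer cycling cells. Whether the drug was in the medium at harvest, how dense the cultures were and whether the line divides more slowly stay open, as does a lasting change of the resistant line.

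Changed long noncoding RNA genes were mostly higher in resistant cells. Over all tested genes of a class, changed or not, the median was 0.94 for bidirectional promoter RNAs (10 higher, 0 lower of 21), 0.45 for antisense RNAs (174 higher, 31 lower of 595) and 0.44 for lincRNAs (160 higher, 38 lower of 542). It was 0.312 for sense-overlapping RNAs (8 higher, 1 lower of 40), 0.179 for processed transcripts (42 higher, 9 lower of 167), 0.059 for genes of the TEC class, whose existence awaits experiments (21 higher, 11 lower of 148) and −0.009 for sense-intronic RNAs (10 higher, 5 lower of 88). Differences between these classes were not tested. Their low level goes with part of the rise and does not account for all of it: 10000 coding gene sets of the same levels had a median of 0.122 and at most 0.181, against 0.338 over all lncRNA genes, an excess of 0.217. More genomic DNA or unspliced RNA in the resistant libraries would raise RNAs that lie inside introns, but 88 sense-intronic genes had a median of −0.009 (95% bootstrap interval over genes −0.18 to 0.10). That interval leaves out the spread between cultures. The share of signal in 6956 coding genes and pseudogenes too low to test was 0.06295% and 0.05157% in parental and 0.06941% and 0.05824% in resistant libraries, a ratio of 1.11 with overlap between groups. At each replicate number the resistant library had the higher share, but no pairing by number is established, so a small rise in background signal is not excluded. What lies behind the excess over coding genes stays open.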
